A study of Gallus gallus with 5 samples.

How the data were processed

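Total RNA was taken from regenerating flight feather follicles of the chicken wing, with 5 follicles pooled per library, per the labels and the design text. Libraries were made with standard Illumina protocols, per the labels' protocols. The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, which the authors computed per gene, with 1 column per library. The submitters' processing notes name TopHat2 2.1.0, Cufflinks 2.2.1 and the genome galGal4. Whether the libraries were scaled against each other, how multiply mapped reads were handled and whether strand was used is not given in the sources used here. FPKM hold no read counts, so depth is unknown and no counting interval is given. The FPKM summed to 986272 and 860352 in the wild-type libraries, 1256070 in the library labelled Wnt5a overexpression, 2097890 in lnc7831 knockdown and 1943370 in lnc3500 knockdown.

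The table holds 17108 Ensembl gene identifiers, 13736 of them paired with another gene name, and names were taken from the table itself. No genomic coordinates were used. Of the 11031 tested genes, 182 were listed at 0 in at least 1 library. An exact 0 in such a table can be a failed estimate, so such genes are given as listed at 0, without a fold. Genes with near-identical copies or several entries of one name, such as HOXA7, ROMO1 and THRSP, are uncertain because reads can be shared between entries.

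Groups follow the labels, with 2 wild-type libraries and 1 library in each of the 3 treated groups. The titles of the wild-type libraries carry the tag T4, which the treated titles lack and the labels do not explain. Whatever it marks cannot be told apart from treatment if the treated libraries differ in it. The wild-type libraries were labelled as repeats, and nothing says whether they came from separate birds. The p-values therefore rest on the spread between these 2 libraries over all genes, which may be technical. FPKM were taken to log2 after adding a pseudocount of 1, and genes with a mean of at least 1 FPKM over the 5 libraries were tested. A fold on this scale understates the change of low genes. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, all 5 libraries in 1 fit, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit has 1 residual degree of freedom, from the wild-type libraries, and each lone treated library is assumed to vary like them. Limma adds variance borrowed from other genes, weighted as 2.64 prior degrees of freedom, so a gene's own spread is the smaller part. Each treated library was compared with wild type, and the treated libraries with each other.

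A size rule without a test counted genes at least 2-fold above both wild-type libraries or at least 2-fold below both. For median centring, an alternative planned before the data were examined, each library was divided by its median ratio to the geometric mean of the libraries. The factors were 0.751 and 0.784 for wild type, 1.16 for the library labelled Wnt5a overexpression, 1.26 for lnc7831 knockdown and 1.19 for lnc3500 knockdown. Relative differences and their standard errors come from the fit to centred values.

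For 30 gene lists fixed before the data were examined (signalling pathways, structural genes and markers of other cell types), the median relative difference was given as a percentile among 10000 random lists of the same size matched in 20 expression bins. The same percentiles against each wild-type library alone, between the wild-type libraries and between treated libraries were added after seeing the data. The correlation and overlap of the comparisons were set beside 100 simulations of unchanged groups with each gene's observed wild-type spread.

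Genes were named by a rule fixed before the data were examined. It takes WNT5A, ACTB and GAPDH, the 10 genes with the largest difference in each direction among those past the size rule, called genes first, and members of the named lists past that rule. Most of the lower genes it took were listed at 0 in some library (9 or 10 of 10 in each comparison), so a second rule, chosen after seeing the data, took the 20 largest on the centred scale among genes above 0 in all 5 libraries. Genes outside both rules, among them PTCH1, SOSTDC1, COL1A2, LY86, MARCO, WNT4 and list members beyond the 2 largest, were chosen after their values were seen. Some genes that these rules select are not reported here.

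The limma step was tested on simulated data for the comparison of the library labelled Wnt5a overexpression with wild type, over 11031 genes, with 200 changed genes and 5 runs. It called 0% of genes changed by 1 or 2 log2 units, 15.2% of those changed by 4 and 82.0% of those changed by 8, with 3.8 false calls on average. The size rule took 35.2%, 88.0%, 99.6% and 99.6% of them and 490.6 unchanged genes on average. These figures rest on variances drawn from the spread that limma fitted. A simpler percentile, among random lists not matched on expression, was tested on the same comparison with lists of 25 genes. Of 100 random lists 6 fell outside the middle 95%, and all 100 lists shifted by 1 log2 unit lay above it. Lists drawn at random do not cover lists whose genes vary together, so the matched percentile was not checked for these.

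Alternatives were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, median centring, quantile normalization, limma without trend or with robust variances, other thresholds, a 3-fold rule, leaving out each wild-type library, and a separate wild-type library for each comparison. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.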

Results

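RNA was profiled in regenerating flight feather follicles of the chicken wing. Follicles were plucked to start regrowth, and lentiviral vectors were used to overexpress or knock down a gene in the follicle. The source name in the labels is dermal papilla, the mesenchymal signalling centre at the base of the follicle, and the tissue is given as feather follicle. Each of the 5 libraries holds RNA of 5 pooled follicles. There were 2 wild-type libraries and 1 library each for Wnt5a overexpression, lnc7831 knockdown and lnc3500 knockdown, the last named for long non-coding RNAs. Each treated group has n = 1, so no difference from wild type has a replicate check of its own, and the spread comes from the 2 wild-type libraries alone. The labels name no library made with an empty vector. Only the wild-type titles carry the tag T4, which the labels do not explain. The values were FPKM for 17108 genes, of which 11031 had a mean of at least 1 FPKM and were tested. Read depth per library is unknown from these values.

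As deposited, the FPKM of most tested genes were higher in the 3 treated libraries than in wild type. FPKM are scaled within each library, so this shift cannot be told apart from a difference in scaling. The median log2 difference as deposited was 0.54 for the library labelled Wnt5a overexpression, 0.64 for lnc7831 knockdown and 0.56 for lnc3500 knockdown, and 87.6%, 93.1% and 90.1% of genes were higher. Gene differences are therefore given relative to the median gene, as log2 values after median centring, with the standard error from limma. FPKM are given as deposited. ACTB, which encodes cytoplasmic beta-actin, had 2578 and 2594 FPKM in wild type, and its relative log2 differences were 0.26, 0.19 and 0.45 in the same order of libraries. GAPDH, a glycolytic enzyme, had relative log2 differences of 0.40, -0.02 and 0.33. The 10 highest genes held between 31.3% and 60.9% of the summed FPKM of a library.

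The wild-type libraries differed from each other by at least 2-fold in 1331 genes after centring, 929 of them higher in wild-type library 2. WNT4 had 18.2 FPKM in wild-type library 1 and 94.1 in library 2. Proliferation genes had a median log2 difference of -0.60 between library 2 and library 1, and interferon-stimulated genes 0.70. Of 30 gene lists fixed before the data were examined, 12 lay outside the middle 95% of random lists matched on expression in this wild-type difference, among them WNT ligands, Notch signalling genes and alpha keratins. Against the wild-type mean, 13, 17 and 11 lists lay outside it in the library labelled Wnt5a overexpression, lnc7831 knockdown and lnc3500 knockdown, so list medians describe single libraries. Against each wild-type library taken alone, the lists outside it on one side were epidermal cell markers, alpha keratins, leukocyte markers and patterning factors in the first library. They were alpha keratins, dermal matrix, retinoic acid, Notch, cell adhesion and inflammatory response genes in lnc7831 knockdown, and epidermal, leukocyte and interferon-stimulated genes in lnc3500 knockdown.

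WNT5A, the ligand of non-canonical WNT signalling named in the first treatment, was measured first in every library. WNT5A (ENSGALG00000005410) had 29.7 and 64.3 FPKM in wild type, 75.7 in the library labelled Wnt5a overexpression, 162 in lnc7831 knockdown and 43.8 in lnc3500 knockdown. Relative to the median gene, its log2 difference from wild type was 0.19 (SE 0.59) in the library labelled Wnt5a overexpression, smaller than the difference of 1.04 between the wild-type libraries. WNT5A thus did not stand out in that library, and every direction given for it belongs to the library as labelled. No gene of the table carries the name of either targeted long non-coding RNA, so neither knockdown was checked.

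**Figure D1:**
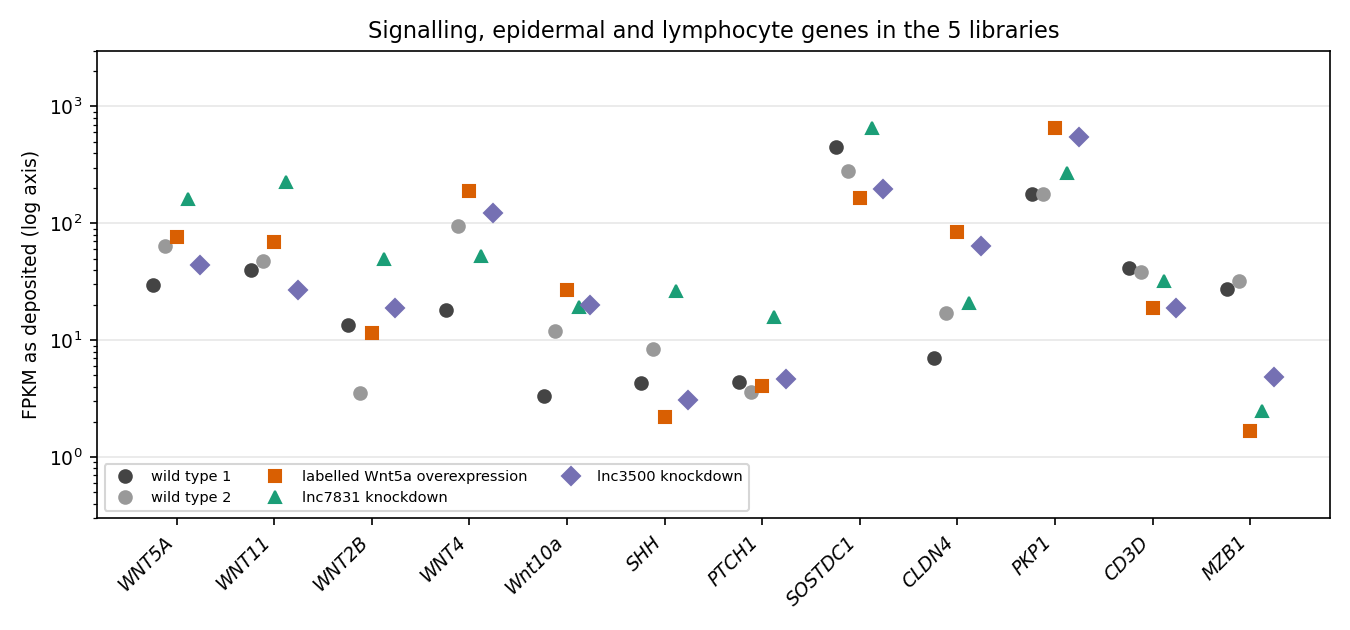
FPKM as deposited, on a log axis, of 12 genes in each of the 5 libraries; each point is 1 library of 5 pooled follicles. WNT5A is highest in lnc7831 knockdown at 162 FPKM, CLDN4 and PKP1 are highest in the library labelled Wnt5a overexpression, and MZB1 lies below both wild-type libraries in all 3 treated libraries.

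The first comparison asked how the library labelled Wnt5a overexpression differed from wild type. Of 24 epidermal cell markers 10 were at least 2-fold above both wild types in it, and of 20 leukocyte markers 4 were at least 2-fold below both. The tight junction gene CLDN4 had 84.4 FPKM against 7.01 and 17.0 in wild type, a relative log2 difference of 2.26 (SE 0.61). The desmosome gene PKP1 had 652 FPKM against 179 and 177, and JUP, which encodes plakoglobin, had 1580 against 339 and 400. MZB1, a gene of plasma and marginal zone B cells, had 1.67 FPKM against 27.3 and 32.3, a log2 difference of -4.03 (SE 0.31), and IGJ, the joining chain of polymeric antibodies, had 8.61 against 90.4 and 68.7.

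Among the epidermal cell markers, 22 lay above the wild-type mean, with a median relative log2 difference of 1.01. Those past the 2-fold rule included the hemidesmosome integrin ITGB4 (1.58) and the epidermal transcription factor TP63 (1.44). None was called by limma over all genes, and 9 were called when adjusted over the list alone on values as deposited, but 0 after centring. Other epithelial genes at least 2-fold above both wild types were the proton pump gene ATP12A (4.35, SE 0.85), the epithelial transcription factor ELF3 (2.26, SE 0.40) and the hemidesmosome collagen COL17A1 (2.36, SE 1.06). The transglutaminase gene TGM6 also passed the rule (2.53, SE 0.70). S100A16 had 13488 FPKM against 1360 and 2277. Six2, a homeobox gene, had 31.7 FPKM in this library, 0.18 and 0.97 in wild type, 2.75 in lnc7831 knockdown and 0.44 in lnc3500 knockdown. The 5 measured alpha keratins had a median of 1.41, which was 0.70 against wild-type library 2 and 2.15 against library 1, with KRT20 at 1.83 (SE 0.59).

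The leukocyte markers had a list median of -0.75, which was -0.92 against wild-type library 2 and -0.43 against library 1, with 0 members at least 2-fold above both wild types. The 4 below both were the B-cell receptor chain CD79B (-1.80), the T-cell receptor component CD3D (-1.64) and the T-cell co-receptors CD8A (-1.55) and CD4 (-1.30). The macrophage genes LY86 and MARCO of the same list were at 0.43 and 0.60. Limb and skin patterning factors had a median of -0.31, and its 2 members past the 2-fold rule were HOXA7 entries listed at 0 in every treated library. They were called when adjusted over the list alone in each of the 3 comparisons, with an adjusted p of 0.0200 in limma, or 0.0148 after centring, while another HOXA7 entry had 20.5 FPKM in this library against 21.6 and 19.6.

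Signalling genes were mixed in this library. SHH, the Hedgehog ligand of the feather epithelium, had 2.22 FPKM against 4.28 and 8.37, a log2 difference of -1.61 (SE 0.47). The WNT and BMP modulator SOSTDC1 had 164 against 447 and 283, and FGF18 had 0.386 against 2.58 and 2.81. WNT7B was the WNT ligand past the 2-fold rule, at 1.14. The 24 non-canonical WNT and planar polarity genes had a median of 0.02 and the 14 beta-catenin target and feedback genes 0.03, with 0 members of either list past the rule. Against wild-type library 2 and library 1 in that order, the medians were 0.03 and 0.01 for the former and -0.44 and 0.26 for the latter. Proliferation genes had a median of -0.41, which was -0.12 against wild-type library 2 and -0.71 against library 1. Hedgehog signalling genes had a median of -0.41, BMP and TGF-beta signalling genes -0.19, and Notch signalling genes 0.35. Against wild-type library 2 and library 1 in that order, these were -0.21 and -0.52, -0.38 and 0.01, and 0.21 and 0.55.

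Limma called 0 genes in this comparison at an adjusted p below 0.05. At an unadjusted p below 0.05 it took 1314 of 11031 genes as deposited and 442 after centring. If no gene differed, a share of 0.05 of the tested genes would be expected to pass. The count after centring lies below that share. The smallest adjusted p as deposited was 0.0608, for ENSGALG00000026592, listed at 0 here and at 200415 and 208769 FPKM in wild type. That gene was called after centring, with an adjusted p of 0.0405, and at 0.000493 to 0.0405 under 5 of the alternative settings. After centring, 240 genes were at least 2-fold above both wild types and 192 below both, against 904 and 109 as deposited. In data simulated for this comparison, 490.6 genes on average passed the same rule among those simulated without a change.

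The second comparison asked how lnc7831 knockdown differed from wild type. Of the 30 dermal matrix genes 25 lay above the wild-type mean in this library, 1 of them at least 2-fold above both wild types, and of the 15 inflammatory response genes 13 lay below it, 2 of them at least 2-fold below both. MOGAT1, an enzyme of triglyceride synthesis, had 141 FPKM against 4.27 and 1.31 in wild type, a relative log2 difference of 4.74 (SE 0.67), and PHYH, a peroxisomal enzyme of branched fatty acid oxidation, had 441 against 18.0 and 25.3, a difference of 3.61 (SE 0.40). WNT11 had 225 FPKM against 39.5 and 47.6, and WNT2B 49.6 against 13.4 and 3.52. The cytokine signalling inhibitor SOCS3 had 20.9 FPKM against 28.3 and 130.

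The dermal matrix genes had a median of 0.45. COL3A1, a fibrillar collagen, had 1421 FPKM against 379 and 280, a difference of 1.41 (SE 0.46), and COL1A2 had 3996 against 1213 and 1003. The 9 measured retinoic acid pathway genes had a median of 0.85, with 5 above the wild-type mean, led by the retinol transporter STRA6 (2.19, SE 0.89) and the retinoic acid binding protein CRABP2 (1.57, SE 0.48). Notch signalling genes had a median of 0.43, with the Notch feedback gene NRARP at 1.92. Cell adhesion molecules of feather morphogenesis had a median of 0.42 with 0 of 22 past the 2-fold rule. The 5 alpha keratins had a median of 1.59, and KRT20 was called when adjusted over the list alone, with an adjusted p of 0.0202 in limma as deposited and 0.0434 after centring. Against wild-type library 2 and library 1 in that order, the medians were 0.44 and 1.10 for retinoic acid genes, 0.29 and 0.77 for Notch genes and 0.68 and 2.08 for alpha keratins. Of 21 dermal papilla markers 14 lay above the wild-type mean, with a median of 0.38, which was 0.14 against wild-type library 2 and 0.35 against library 1. The phosphatase gene ALPL, with 190 FPKM against 23.8 and 37.1, was the 1 past the 2-fold rule.

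The 12 measured WNT ligands had a median of 0.83, which was 0.07 against wild-type library 2 alone and 1.30 against library 1 alone. WNT11 (1.64, SE 0.37), WNT2B (1.99) and WNT7B (1.20) were at least 2-fold above both wild types. WNT11 and WNT7B were called when adjusted over the list alone as deposited, each with an adjusted p of 0.0339 in limma, and 0 ligands after centring. SHH had 26.1 FPKM against 4.28 and 8.37, and the Hedgehog receptor gene PTCH1 had 15.9 FPKM against 4.41 and 3.58. Their relative log2 differences were 1.30 for SHH and 1.14 for PTCH1, with 0 of 11 Hedgehog signalling genes at least 2-fold above both wild types. Proliferation genes had a median of 0.27, which was 0.52 against wild-type library 2 and 0.02 against library 1, and the ubiquitin enzyme gene UBE2C was past the rule at 1.28. The patterning gene MSX1 was at 1.37 and was called over its list alone as deposited, with an adjusted p of 0.0250 in limma, but not after centring.

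Inflammatory response genes had a median of -0.76, with SOCS3 (-2.19, SE 1.01) and IL1RL1 (-1.55, SE 0.40) past the rule. Leukocyte markers had a median of -0.34, which was -0.60 and -0.16 against wild-type library 2 and library 1, and interferon-stimulated genes -0.54, which was -0.83 and -0.16. The 24 epidermal cell markers had a median of 0.28, which was 0.54 against wild-type library 2 and 0.27 against library 1, with 17 above the wild-type mean and 2 past the 2-fold rule. MZB1 had 2.46 FPKM against 27.3 and 32.3. The pigment gene TYRP1 had 14.1 FPKM against 3.01 and 0.191, and the hormone precursor gene Pomc had 209 against 33.4 and 3.14. HBG2, the measured red blood cell gene, had 56.9 FPKM against 12.6 and 10.6, a difference of 1.52, and was not called by limma over all genes. Its list has 1 measured member, so the limma p adjusted over the list alone is the unadjusted one, 0.00356 as deposited and 0.0143 after centring here, and 0.0297 as deposited and 0.203 after centring in lnc3500 knockdown.

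At an unadjusted p below 0.05, limma took 1620 genes in this comparison as deposited and 335 after centring. The latter is again below the share of 0.05 expected if no gene differed. After adjustment it called 4, and all 4 were listed at 0 in both wild types. Their own wild-type spread was therefore 0, and their limma p-values rest on variance borrowed from other genes. The 4 were both entries of the small nucleolar RNA SNORA62 at 6176 and 6787 FPKM, the microRNA gene gga-mir-3523 at 2999 and ENSGALG00000028891 at 466058, with adjusted p from 0.0125 to 0.0214. ENSGALG00000026592 was listed at the same 466058 FPKM in this library and at 200415 and 208769 in wild type. Whether these entries overlap was not checked. The microRNA gene was also at 1329 FPKM in lnc3500 knockdown. In data simulated for the first comparison, limma called 3.8 unchanged genes on average. With a pseudocount of 0.1 or without the expression filter, 0 genes were called. After centring, 181 genes were at least 2-fold above both wild types and 146 below, against 1154 and 78 as deposited.

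The third comparison asked how lnc3500 knockdown differed from wild type. Of 24 epidermal cell markers 5 were at least 2-fold above both wild types in this library, and 7 of 20 leukocyte markers and 2 of 17 interferon-stimulated genes were at least 2-fold below both. CLDN4 had 64.0 FPKM against 7.01 and 17.0, a relative log2 difference of 1.84 (SE 0.61), and the cadherin CDH1 had 179 against 30.9 and 48.1, a difference of 1.56. CD3D had 18.8 FPKM against 41.8 and 38.6. EPSTI1, an interferon-stimulated gene, had 4.53 FPKM against 8.13 and 17.1, a difference of -1.78 (SE 0.52).

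The epidermal cell markers had a median of 0.66, with 21 above the wild-type mean. The 5 past the rule were CLDN4, CDH1 (1.56), ITGA6 (1.38), JUP (1.26) and PKP3 (1.08). The leukocyte markers had a median of -1.02, with 19 below the wild-type mean. CD3D (-1.67), the myeloid and B-cell transcription factor SPI1 (-1.58), CD3E (-1.48) and the pan-leukocyte phosphatase PTPRC (-1.37) were among the 7 past the rule. The interferon-stimulated genes had a median of -0.84, which was -1.05 against wild-type library 2 and -0.53 against library 1, with EPSTI1 and DTX3L (-1.29) past the rule. In each of these lists limma called 0 members over all genes and 0 when adjusted over the list alone.

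Outside the lists, the placental growth factor gene PGF had 71.2 FPKM against 6.45 and 10.2, and the nuclear receptor NR4A3 had 38.6 against 3.41 and 4.18, a relative log2 difference of 2.49 (SE 0.32). The steroid enzyme gene HSD3B2 had 37.2 FPKM against 0.123 and 5.23. TGFBI, an extracellular matrix gene, had 550 FPKM against 91.0 and 145. WNT11 had 26.9 FPKM against 39.5 and 47.6 and was the WNT ligand at least 2-fold below both wild types on the centred scale, at -1.29 (SE 0.37). INHBB, an activin subunit, had 0.279 FPKM against 4.58 and 2.63. The 10 smooth muscle markers lay above the wild-type mean without exception, with a median of 0.41 and 0 past the 2-fold rule. THRSP, a regulator of lipid synthesis, had 1.89 FPKM in this library and 0.527 in the library labelled Wnt5a overexpression, but 117 and 7.83 in wild type, and a second entry of that name did not lie below wild type.

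Limma called 0 genes in this comparison, and the smallest adjusted p as deposited was 0.126. At an unadjusted p below 0.05 it took 1293 genes as deposited and 340 after centring, the latter also below the share of 0.05 expected if no gene differed. After centring, 158 genes were at least 2-fold above both wild types and 181 below, against 901 and 87 as deposited. By the same rule wild-type library 1 differed from wild-type library 2 together with a treated library in 671 to 727 genes, and wild-type library 2 from library 1 together with a treated library in 267 to 295, on either side of the 327 to 432 genes of the treated libraries against both wild types.

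**Figure D2:**
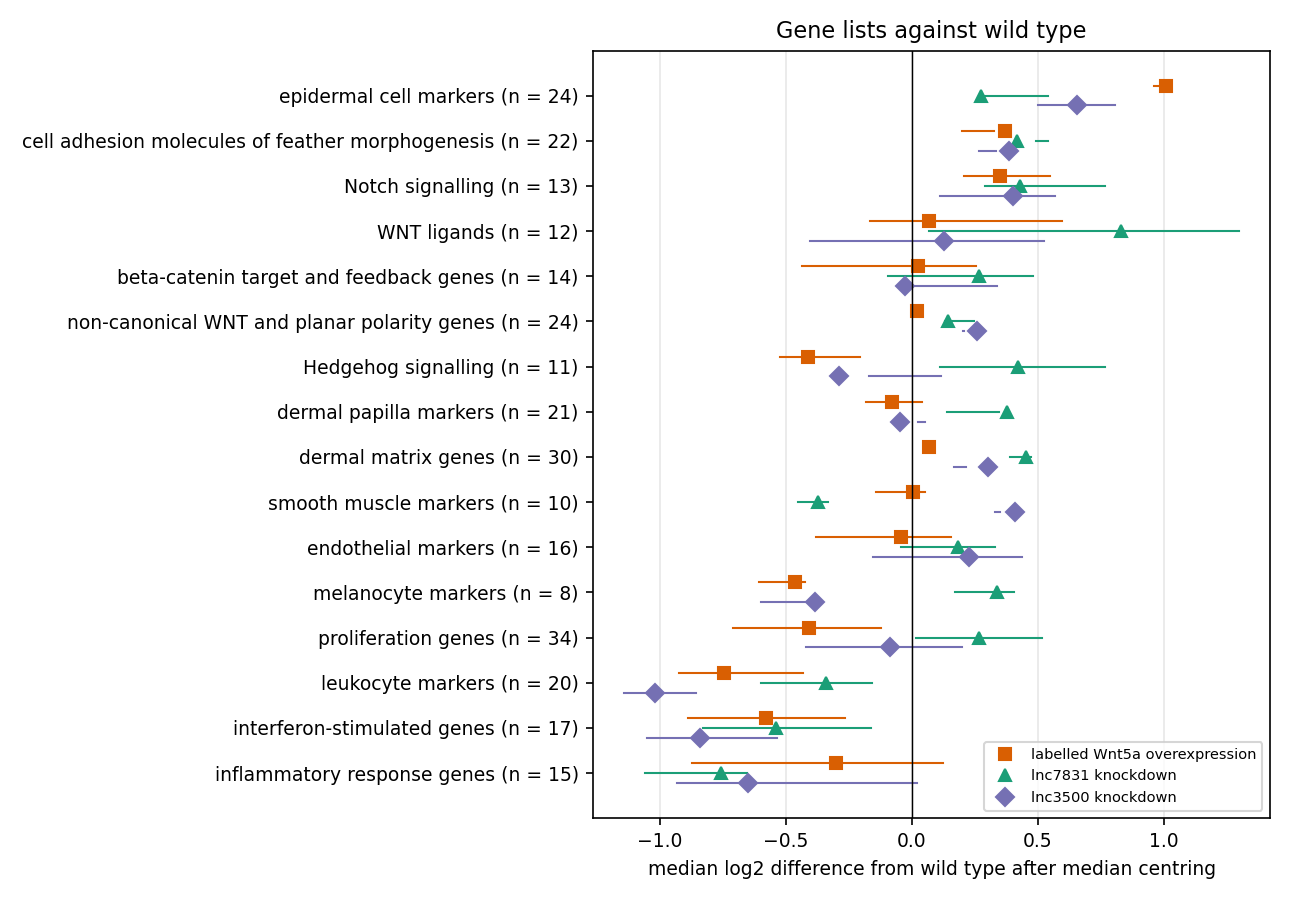
Median log2 difference from wild type after median centring for 16 gene lists in the 3 treated libraries; points use the mean of both wild-type libraries, and lines join the medians taken against each wild-type library alone. Epidermal cell markers lie highest in the library labelled Wnt5a overexpression at 1.01, leukocyte markers lie lowest in lnc3500 knockdown at -1.02, and the line for WNT ligands in lnc7831 knockdown runs from 0.07 to 1.30.

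The treated libraries were also compared directly, without the wild type. SHH had 26.1 FPKM in lnc7831 knockdown, 3.11 in lnc3500 knockdown and 2.22 in the library labelled Wnt5a overexpression. WNT11 was higher in lnc7831 knockdown than in lnc3500 knockdown by a relative log2 difference of 2.93 (SE 0.43), Pomc by 5.73 (SE 1.69) and MOGAT1 by 3.84 (SE 0.77). In lnc7831 knockdown relative to lnc3500 knockdown, leukocyte markers had a median of 0.68, WNT ligands 0.53, proliferation genes 0.39 and smooth muscle markers -0.63. Wild-type library 2 minus library 1 gave 0.23, 0.94, -0.60 and 0.06 for these lists. In the library labelled Wnt5a overexpression, relative to lnc7831 knockdown, epidermal markers had a median of 0.42, proliferation genes -0.68, dermal papilla markers -0.48 and dermal matrix genes -0.50. The same wild-type difference was -0.07, -0.60, 0.04 and -0.11 for them. SLURP1, which encodes a secreted keratinocyte protein, had 587 FPKM in the library labelled Wnt5a overexpression against 61.3 in lnc7831 knockdown.

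None of these named genes was called. Limma called 3 genes between lnc7831 and lnc3500 knockdown, both SNORA62 entries and ENSGALG00000028891, against 260 at an unadjusted p below 0.05. It called 5 between the library labelled Wnt5a overexpression and lnc7831 knockdown, against 303 unadjusted, namely the same 3 with gga-mir-3523 and ENSGALG00000026592. The last had 633633 FPKM in lnc3500 knockdown. Between the library labelled Wnt5a overexpression and lnc3500 knockdown 0 genes were called, against 79 unadjusted. Each of these unadjusted counts lies below the share of 0.05 of tested genes expected if none differed. With a pseudocount of 0.1 or without the expression filter each of these counts was 0.

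The differences from wild type were then set side by side. ATP12A, ELF3, EBP, PROM2, PHGDH and S100A16 were at least 2-fold above both wild types in all 3 treated libraries, and MZB1, IGJ and OTULIN at least 2-fold below. CLDN4, JUP, PGF and SERPINA12 passed the rule upward, and CD3D, SOSTDC1, TGM4 and GZMM downward, in the library labelled Wnt5a overexpression and lnc3500 knockdown but not in lnc7831 knockdown. In the direct comparisons, limma called none of these genes between lnc7831 knockdown and either other treated library. The library labelled Wnt5a overexpression and lnc3500 knockdown were the closest pair, with 192 genes at least 2-fold apart, while the other pairs of libraries had 660 to 1499.

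The correlation across genes, which are not independent replicates, of the differences from wild type was 0.78 between the library labelled Wnt5a overexpression and lnc3500 knockdown. It was 0.50 between that library and lnc7831 knockdown, and 0.55 between the knockdowns. Unchanged groups simulated against the same wild-type libraries gave 0.34, 0.34 and 0.33. The simulated treated libraries were given the wild-type spread. Across genes, the standard deviation of the log2 difference was 0.76 between the wild types, 0.44 between the first pair, and 0.68 and 0.63 between the others. Treated libraries that vary less would correlate more through the shared wild types. The simulated correlations and counts of shared genes are therefore not a matched baseline. The covariance was 0.34 for the first pair against a simulated 0.15, and 0.23 and 0.24 against 0.15 and 0.15 for the others. With a separate wild-type library for each comparison, it was 0.186 and 0.210 for the first pair, 0.0495 and 0.125 for the second and 0.115 and 0.0641 for the knockdowns. The first pair shared 110 genes above and 117 below both wild types, against 57.6 and 57.3 simulated and 3.44 and 3.15 for independent lists. The library labelled Wnt5a overexpression and lnc7831 knockdown shared 63 and 93, against 57.3 and 58.0 simulated and 3.94 and 2.54 for independent lists. The knockdowns shared 46 and 88, against 57.0 and 57.3 simulated and 2.59 and 2.40 for independent lists. The simulated lists held 223.6 to 228.4 genes on average and the observed lists 146 to 240, so the counts of shared genes are not matched for list length. Where the correlations and counts of shared genes lie above the simulated ones, part of the excess may come from the shared wild-type libraries, which are too few to be split with 2 libraries on each side. The simulated covariances already hold the shared wild-type term.

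**Figure D3:**
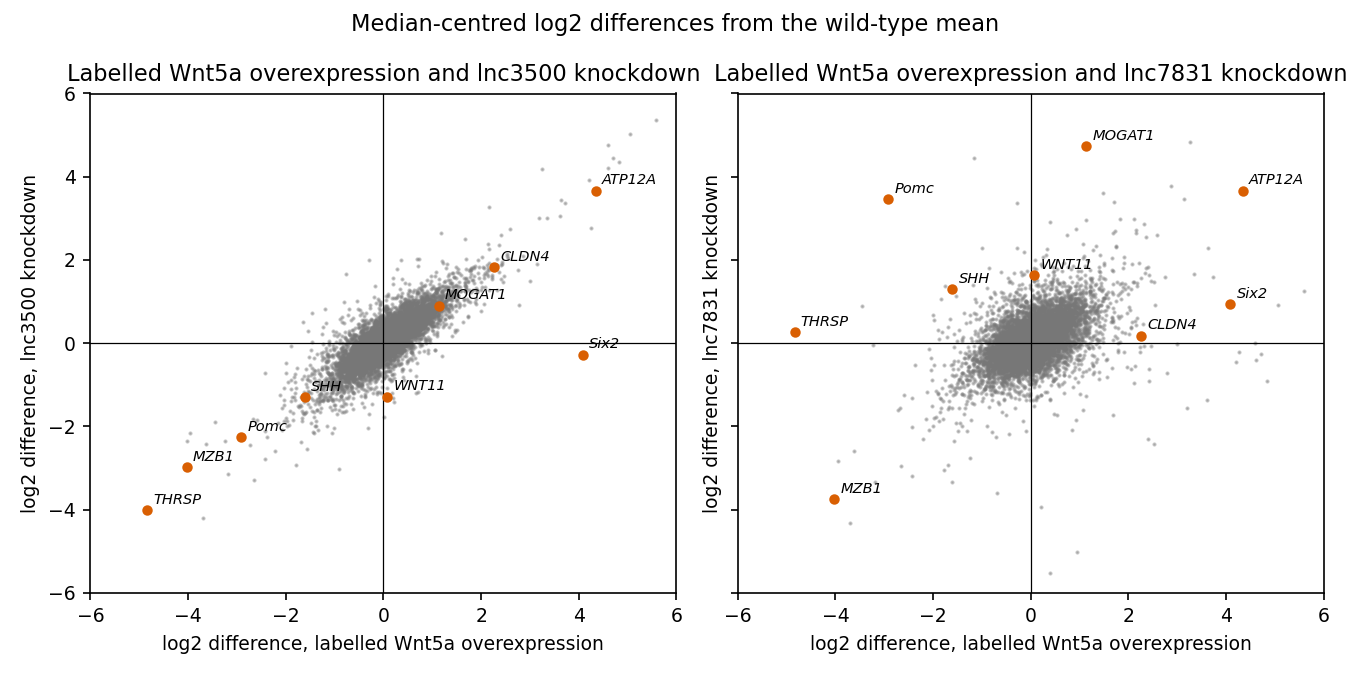
Relative log2 difference from the wild-type mean of each tested gene above 0 in all 5 libraries, with the library labelled Wnt5a overexpression on the horizontal axes and lnc3500 knockdown (left) or lnc7831 knockdown (right) on the vertical axes; grey points are genes and orange points named genes. The correlation over all tested genes is 0.78 on the left and 0.50 on the right, with SHH, WNT11 and MOGAT1 higher on the right.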

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

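The rule that keeps only genes above 0 in all 5 libraries, and leaving out a wild-type library for the centred list medians, were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because only the wild-type group has more than 1 library. Leaving out a wild-type library leaves no residual degree of freedom, so limma's calls were not recomputed that way. In the order library labelled Wnt5a overexpression, lnc7831 knockdown and lnc3500 knockdown, limma called 0, 4 and 0 genes against wild type. At an unadjusted p below 0.05 it called 1314, 1620 and 1293 as deposited, and 442, 335 and 340 after centring. The larger counts come from values on which most genes lay above wild type. The counts after centring lie below the share of 0.05 of tested genes expected if none differed. For the first library, 1 gene was called with a mean of at least 5 FPKM, median centring, quantile normalization, no trend, robust variances or an adjusted p below 0.1 (ENSGALG00000026592 in each), and for lnc3500 knockdown 1 gene with quantile normalization (gga-mir-3523). For lnc7831 knockdown the count was 0 with a pseudocount of 0.1 and 0 with no filter. Between treated libraries, the counts of 3 (lnc7831 and lnc3500 knockdown) and 5 (labelled Wnt5a overexpression and lnc7831 knockdown) were also 0 under those 2 settings, and 260 and 303 unadjusted. Between the library labelled Wnt5a overexpression and lnc3500 knockdown, 79 genes were called unadjusted, 2 with quantile normalization (the same pair) and 1 (ENSGALG00000026592) with a mean of at least 5 FPKM, no trend, robust variances or an adjusted p below 0.1. The cause was not tested.

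The size rule gave 1013, 1232 and 988 genes as deposited. It gave 432, 327 and 339 with median centring, 407, 339 and 335 with quantile normalization, 278, 265 and 202 at 3-fold, and 332, 240 and 256 with centring and genes above 0 in all 5 libraries. Without a wild-type library it ranged from 1793 to 2869, 2172 to 3287 and 1790 to 2948, a larger count that follows from having 1 library to pass. With centring, the counts above and below both wild types were 240 and 192, 181 and 146, and 158 and 181, in place of 904 and 109, 1154 and 78, and 901 and 87. With a separate wild-type library for each comparison, the correlation of 0.50 between the first library and lnc7831 knockdown became 0.077 and 0.22, that of 0.78 with lnc3500 knockdown became 0.32 and 0.37, and that of 0.55 between the knockdowns became 0.21 and 0.11. Of 90 list medians on the centred scale of the report, 36 moved by at least 1 SD between the wild-type libraries without wild-type library 1 and 38 without library 2, and 73 kept their sign in each case. Of the 90 on the scale as deposited, 78 moved with median centring, 17 with a pseudocount of 0.1, 37 without wild-type library 1 and 32 without library 2, and 64, 89, 85 and 83 kept their sign. Of 170 differences of named genes as deposited, 87, 86, 7 and 7 moved by at least 1 SD of the gene between the wild-type libraries. Depth is unknown and limits no value here in a way that could be computed.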

Other observations

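The tests of the split counts, the 0 entries, the marker lists, the interferon list and the label swap were chosen after the results were seen, and the separate wild-type references were planned. Beyond the comparisons above, other lists are given as medians in the order library labelled Wnt5a overexpression, lnc7831 knockdown and lnc3500 knockdown, first against the wild-type mean, then against wild-type library 2 alone and library 1 alone. Ribosomal protein genes had medians of 0.10, -0.27 and -0.02, against library 2 0.30, -0.11 and 0.19, and against library 1 -0.10, -0.50 and -0.24, with 43 of 63 members below both wild types in lnc7831 knockdown. The 8 measured melanocyte markers had medians of -0.46, 0.34 and -0.38, against library 2 -0.42, 0.17 and -0.36, and against library 1 -0.60, 0.41 and -0.60. Mitochondrially encoded genes had medians of 0.34, 0.23 and 0.32, against library 2 0.25, -0.02 and 0.17, and against library 1 0.52, 0.21 and 0.40. Immediate early and heat shock genes had -0.06, 0.40 and 0.08, against library 2 -0.13, 0.16 and 0.07, and against library 1 -0.16, 0.23 and 0.17.

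Further lists are given in the same order. Endothelial markers had medians of -0.04, 0.18 and 0.23, against library 2 -0.38, -0.04 and -0.15, and against library 1 0.16, 0.33 and 0.44. FGF signalling genes had -0.11, -0.06 and -0.03, against library 2 -0.37, -0.29 and -0.05, and against library 1 0.08, 0.05 and 0.26. WNT receptors and secreted modulators had 0.02, 0.19 and 0.07, against library 2 -0.23, 0.14 and -0.01, and against library 1 0.02, 0.44 and 0.20. Reference housekeeping genes had 0.24, -0.09 and 0.05, against library 2 0.28, 0.14 and 0.18, and against library 1 0.11, -0.22 and -0.03. The 5 measured skeletal muscle markers had -0.45, -0.29 and 0.29, against library 2 -0.02, -0.03 and 0.03, and against library 1 -0.88, 0.14 and -0.14. The 2 measured feather beta keratins had 1.52, 0.42 and 0.34, against library 2 0.02, -1.08 and -1.17, and against library 1 3.02, 1.92 and 1.84. Apoptosis and p53 genes had 0.09, 0.04 and 0.01, and stayed between 0 and 0.18 against either library. The metallothionein gene MT1 had 40219 and 11645 FPKM in wild type and 8118 in lnc7831 knockdown, and MT4 had 4981 and 1674 against 1308. CRH, which encodes corticotropin-releasing hormone, had 60.7 FPKM in lnc7831 knockdown against 15.6 and 3.82 in wild type, beside the higher Pomc.

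The differences of the library labelled Wnt5a overexpression and of lnc3500 knockdown correlated across genes, with epidermal medians of 1.01 and 0.66 and leukocyte medians of -0.75 and -1.02. In lnc7831 knockdown the epidermal median was 0.28, or 0.54 and 0.27 against wild-type library 2 and library 1 alone, and the leukocyte median -0.34, or -0.60 and -0.16. Shared wild-type libraries do not account for all of the correlation, which was 0.32 and 0.37 with a different wild-type library for each comparison. A larger share of epidermis alone would lower every other cell type alike. The values of the single lnc3500 knockdown library argue against this. Its leukocyte minus dermal matrix medians were -1.32 and, against wild-type library 1 alone, -1.02 (permutation of genes, two-sided p 2e-05 for each, the smallest these permutations can give). It stays open in the library labelled Wnt5a overexpression, with -0.81 (same permutation, p 4e-05) and, against library 1 alone, -0.48 (p 0.06). Genes of a list are not independent replicates, so these p-values do not measure spread between libraries. The dermal matrix median alone was 0.07 in the library labelled Wnt5a overexpression, or 0.04 and 0.05 against wild-type library 2 and library 1. In lnc3500 knockdown it was 0.30, or 0.22 and 0.17, so higher dermal matrix genes gave part of the difference there. Wild-type library 2 minus library 1 gave a leukocyte median of 0.23 and a dermal matrix median of -0.11. More epidermis together with fewer leukocytes may still be a source, as may dissection, a common response to the vector, or a day or batch the labels do not give, none of which was separated from the treatments with 1 library each.

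Genes separating the 3 treated libraries from both wild types by at least 2-fold numbered 115, 32 higher and 83 lower, and the highest of the other splits of the 5 libraries into 2 and 3 gave 64. Of the 10 splits, 1, the real one, gave as many, and so few splits cannot give a share under 0.05. Among tested genes, 36 were listed at 0 on one side and at 1 FPKM or more in every library of the other, against at most 9 in other splits, and 33 of the 36 were 0 in the treated libraries, such as an entry of ROMO1 at 679 and 352 FPKM in wild type while another entry had 69.8 to 182 in all 5. That is consistent with a library or processing batch that follows the groups, which cannot be told apart from treatment or vector here. The interferon list had medians of -0.16 or lower in each treated library against each wild-type library. Resampling the genes of the list gave intervals whose highest upper bound was -0.02. Of its 17 members, 0 lay above both wild types in any treated library. In the library labelled Wnt5a overexpression, lnc7831 knockdown and lnc3500 knockdown, 13, 12 and 14 lay below both. The list was thus not raised relative to the median gene in any treated library. The test required medians outside the middle 95% of random lists, which was not met in each case. The labels name no empty-vector library, and leukocyte medians were lower in the same libraries. An interferon response to the vector therefore stays open. Whether the list fell is less clear, as the medians reached percentile 10.02 of random lists and the wild-type libraries differed by 0.70 on it.

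WNT5A had 162 FPKM in lnc7831 knockdown and 75.7 in the library labelled Wnt5a overexpression, a relative log2 difference of -0.97 (SE 0.68) for the latter minus the former, smaller in size than the 1.04 between the wild-type libraries. A swap of these labels would put WNT5A among the largest increases of the former. It stood at percentile 97.2 of tested genes there and 66.7 in the library labelled Wnt5a overexpression, which is neither among the largest 0.5% nor below percentile 95, the bounds set for the test, and leaves the swap open. A low share of infected cells, a vector transcript without the measured region, or an effect of the knockdown on WNT5A may account for it as well, and none was tested.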
